A study of Rattus norvegicus with 8 samples.

How the data were processed

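miRNA was measured on Agilent rat miRNA arrays in 8 samples: the immortalised mesothelial cell culture RPMC, the mesothelial tissue MTC, 4 epithelioid tumours (EM) and 2 sarcomatoid tumours (SM). Per the labels' protocols, RNA was extracted with a miRNeasy kit, and tumours were collected by an age of 26.7 months. Each array carried 938 probes for 350 miRNAs on 7000 spots and was hybridised with 1 Cy3-labelled sample. All 8 arrays lay on 1 slide read in 1 scan, per the file headers, in 2 rows: RPMC, EM 1, SM 1 and SM 2 in the first, and MTC, EM 2, EM 3 and EM 4 in the second.

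The deposited scanner files hold linear spot intensity, background-subtracted by Agilent Feature Extraction 9.5.1.1 with spatial detrending, per the file headers; the submitters' processing notes name version 9.5. The flags for detection, background, saturation and outliers were deposited in the same files as 0 or 1, per the file headers. The arrays were not normalized to each other in these files. The deposited value table holds log2 values that the authors made by a process not given in the sources used here. Set against the scanner values, it was the log2 total signal per miRNA minus 1 constant per array, equal to the 90.6 to 91.1 percentile, with undetected miRNAs at 1 minimum per array. Within a tolerance of 0.01, 63.8 to 72.7% of detected miRNAs matched this on each array, and 100% of those in the top quartile of signal. The remaining dimmer miRNAs were mostly lower in the table for a reason that stayed unknown. The table's medians were -11.8 (RPMC), -6.10 (MTC), -7.09 (EM 1), -6.47 (EM 2), -6.75 (EM 3), -6.72 (EM 4), -8.79 (SM 1) and -14.0 (SM 2).

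From the intensity files, control spots and spots with an outlier flag (2.81 to 3.56% of spots) were left out, spots of a probe were averaged, and probes of a miRNA were summed. The result was divided by each array's 75th percentile over the 101 miRNAs detected on all 8 arrays, the scaling signal. It was then floored at 0.00503 of the scaling signal (-7.64 in log2 units), the median over arrays of the 5th percentile of detected signals, and log2 was taken last. No spot was saturated. Between 109 and 222 miRNAs per array were well above background on most spots of a probe. For dim miRNAs the floor limits what can be measured, and the number of arrays limits the precision. The floor lay above the signal of 20, 34, 13 and 1 detected miRNAs in EM 1 to EM 4. It did so for 31 in SM 1, 6 in SM 2 and 0 in RPMC and in MTC, so a value at the floor is not always an undetected miRNA. Where a miRNA was not detected on any array of a group, the difference is given as at least a fold. This sets the mean of the brighter group against the dim group's mean of, per array, the higher of the lowest detected signal and the miRNA's own.

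Groups were compared with limma 3.58.1 in R 4.3.3, with files read by the data.table package, version 1.17.8, by lmFit and eBayes, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. miRNAs detected on at least 2 arrays of a fit were tested. SM against EM was fitted on the 6 tumours alone. EM, SM and their mean against the non-neoplastic pair were fitted on all 8 arrays with 1 shared spread. MTC and RPMC, with 1 array each, were compared without a test. For 19 lists of miRNAs fixed before the data were examined, camera was run on the lists with at least 3 tested members, with a preset correlation of 0.01, adjusted over the lists. The other set tests were camera with an estimated correlation and fry. The latter tests only whether a list's miRNAs move one way on balance, against 0 and not against the other miRNAs. The lists overlap: miR-155 stands with leukocytes and the singles, and the iron list shares miR-485 with Dlk1-Dio3, miR-200b with the miR-200 family, let-7d with let-7 and miR-210 with the singles. Of the marker lists of other cell types, RPMC had 2 of 2 smooth muscle miRNAs detected, 3 of 8 neural, 2 of 7 leukocyte, 1 of 7 striated muscle, 2 of 5 squamous and gland, 1 of 2 endothelial, 0 of 2 erythroid and 0 of 7 liver, pancreas and gut ones.

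The rule for named miRNAs, fixed before the data were examined, took in each comparison the 12 largest rises and falls past the threshold, or the 8 highest and 8 lowest moderated statistics where under 10 passed. It also took the miR-199/miR-214 list, miR-31, miR-21, the miR-34 family and up to 4 members of each other list, and for MTC and RPMC the 8 largest ratios each way. To limit length, the text names 2 members per list for SM against EM, 1 for the mean of tumours and 0 for the other 2 comparisons against non-neoplastic samples. That reduction was set after the values and the number of direction changes had been seen. The brightest miRNA of each array, the unscaled signals of miR-1, miR-122 and miR-451, and the miRNAs on which single arrays are described in the closing observations were chosen after their values were seen.

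The procedure was tested on simulated data with 40 changed miRNAs in 50 runs. For SM against EM, at the 63.7% of miRNAs tested, it recovered 21.8%, 51.6%, 71.0% and 84.6% of changes of 1, 2, 3 and 4 in log2 units, with 5.14% of calls false. For the mean of tumours against non-neoplastic samples, with 241 miRNAs, it recovered 8.00%, 41.8%, 65.6% and 76.6%, with 5.13% false. The simulated noise was independent between miRNAs, had the same spread in all groups, and was made without the scaling or the floor. The real arrays differ in these respects, so these shares do not give the share of false calls in the results. The alternatives fixed beforehand covered the scaling, normexp background correction with an offset of 50, the summary per miRNA, the floor and the filter on dim miRNAs. They also covered the authors' table, the variance model, the samples in the fit, each array left out in turn, and the replicate number as a block. The slide row as a block and a filter at an unscaled geometric mean of 100 were added after the data were examined. Leaving out an array of a pair leaves 1, which is then assumed to vary like the other groups. Probe positions are those of the files in the rn4 build. The gene table at hand is of assembly GRCr8, so no position was taken from it. It places the genes Mir199a2, Mir214, Mir181a-1 and Mir181b1 on chromosome 13 and Mir322 and Mir503 on X.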

Results

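miRNA levels were measured in rat peritoneal mesothelioma of 2 histological subtypes and in non-neoplastic mesothelial samples, to find miRNAs that set the subtypes apart from each other and the tumours apart from mesothelium. Each of the 8 samples was hybridised to 1 single-colour array carrying probes for 350 rat miRNAs. The tumours arose in F1 hybrids of the Fischer344 and Brown-Norway strains after intraperitoneal injection of iron saccharate, an iron-sugar complex, at 5 mg iron per kg on 5 days a week for 12 weeks from 4 weeks of age, with nitrilotriacetate, an iron chelator, at 80 mg/kg for 20 weeks. The tumours comprised 4 of the epithelioid subtype (EM 1 to EM 4) and 2 of the sarcomatoid subtype (SM 1 and SM 2), the spindle-celled subtype. The non-neoplastic group held 1 array of an immortalised peritoneal mesothelial cell culture (RPMC) and 1 of collected mesothelial tissue (MTC). The labels attach the same injection protocol to all samples, so the exposure of these 2 was not settled. Nothing in the labels says that the tumours came from separate animals, so p-values measure the spread between these samples.

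Between 156 and 237 miRNAs were detected on each tumour array, 130 in RPMC and 204 in MTC, and 101 were detected on all 8 arrays. The signal used for scaling lay between 3049 and 7122 intensity units on the tumour arrays, at 1008 in MTC and at 597 in RPMC. miR-21, a miRNA raised in many cancers, was the brightest miRNA in RPMC, EM 1, EM 3, SM 1 and SM 2. The brightest in EM 2 was miR-29a, in EM 4 the striated muscle miRNA miR-1, and in MTC miR-494, which took 37.2% of the summed signal of that array. Pearson's r of the log2 values was taken across all 350 miRNAs, which are not independent replicates. It was 0.893 to 0.933 between EM arrays, 0.921 between the SM arrays and 0.714 between RPMC and MTC. Between EM and SM arrays it was 0.831 to 0.931. EM 1 and SM 1, in the same slide row, had 0.931, above the SM pair, so whole profiles did not group strictly by subtype.

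Sarcomatoid tumours were compared with epithelioid tumours to find miRNAs that differ by subtype. The members of the miR-199/miR-214 cluster, encoded together on chromosome 13 and abundant in mesenchymal cells, were higher in the sarcomatoid tumours, each by over 8-fold. miR-214 was 12.1-fold higher (1.42 ± 0.029, SD, n = 2, against -2.17 ± 0.64, SD, n = 4, in log2 units relative to the scaling signal), miR-199a-5p 9.41-fold and miR-199a-3p 8.69-fold. A second pair, miR-181b and miR-181a, whose probes the files place on the same chromosome, was 8.48-fold and 5.94-fold higher. Which gene their signal came from was not tested. miR-152 rose 3.54-fold and miR-674-3p, detected on only 2 of the EM arrays, 3.25-fold. miR-101b, whose family targets the methyltransferase Ezh2, was 3.14-fold lower (-3.57 ± 0.24, SD, n = 2, against -1.92 ± 0.24, SD, n = 4).

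In all, 9 of the tested miRNAs (63.7% of the 350) passed the limma test, 8 higher and 1 lower in the sarcomatoid tumours, and 47 had an unadjusted p under 0.05. The adjusted p was 0.00813 for miR-199a-3p (log2 difference 3.12, SE 0.26), 0.0193 for miR-214 (SE 0.44), 0.00813 for miR-181b (SE 0.27), 0.0449 for miR-152 and 0.0243 for miR-101b. The passenger strand miR-181a* was not detected on any EM array and was at least 1.99-fold higher in SM (adjusted p = 0.0449). Of the alternatives in which each was tested, the call was lost in 17 of 23 for miR-152, 15 of 21 for miR-674-3p, 13 of 19 for miR-181a*, which turned in 1 more, and 11 of 23 for miR-101b. In the rn4 build, the probes of miR-199a-3p and miR-199a-5p lay at chromosome 13, 77910801 to 77910857, those of miR-214 at 77916261 to 77916275, and those of miR-181a and miR-181b at 51132539 to 51132735 on the same chromosome, while miR-101b lay at chromosome 1, 232779646 to 232779664, and miR-152 at chromosome 10, 85608302 to 85608317. The median log2 difference of all tested miRNAs was -0.25, and relative to it miR-214 was 3.85 higher and miR-101b differed by -1.40. RPMC had 3.30 for miR-214, 2.59 for miR-199a-3p and -0.011 for miR-199a-5p, and MTC had -1.44, 0.48 and -3.64.

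Without SM 1 no miRNA passed limma's test (25 at an unadjusted p under 0.05), and without EM 4 the number was 4. With all 8 samples in the fit 2 passed, and with the replicate number as a block 0 by limma (20 at an unadjusted p under 0.05). The slide held its arrays in 2 rows, with EM 1 and both SM arrays in the first of them. With the row as a block 1 miRNA passed, while the median difference of the miR-199/miR-214 cluster was 3.63. Since the other row held no SM array, the blocked difference is that of SM minus EM 1 alone. It was 4.21 for miR-214, 3.58 for miR-199a-3p, 2.86 for miR-181b and -1.53 for miR-101b. The split of higher to lower calls was 8 to 1 with the scaling used, 5 to 0 with the percentile over all miRNAs, 11 to 4 with quantile normalization, 7 to 13 with median scaling and 6 to 24 in the authors' value table.

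**Figure D1:**
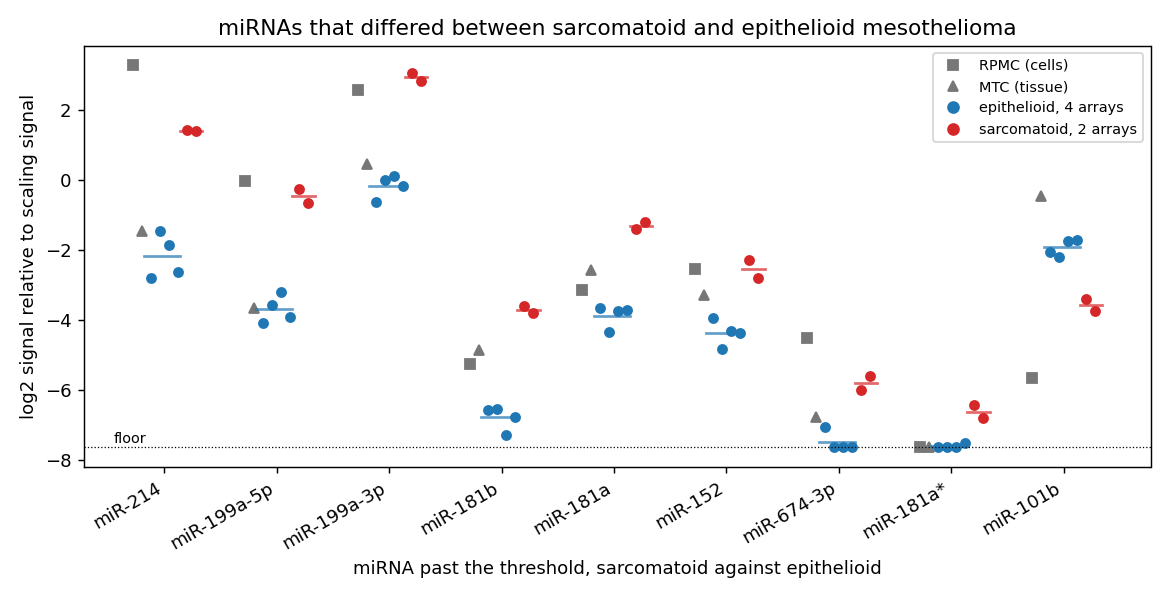
Each point is 1 array, and the vertical axis gives the log2 signal relative to the scaling signal for the 9 miRNAs that passed the test of SM against EM; horizontal lines are group means of EM (n = 4) and SM (n = 2), and the dotted line is the floor. Both SM arrays lie above all 4 EM arrays for the 8 higher miRNAs and below them for miR-101b.

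Of 16 lists with enough members for a set test, 6 passed camera with its preset correlation in SM against EM. All 3 members of the miR-199/miR-214 cluster rose (median log2 difference 3.23, adjusted p = 0.000114, but 0.440 with an estimated correlation), and all 3 also passed when adjusted over the list alone. This cluster is known as the subject of the study, so its list is not independent evidence of its direction. By fry 4 of the lists passed. With an estimated correlation none did. The miR-322/miR-503 cluster of the X chromosome, whose miRNAs restrain the cell cycle, was higher as a set (median 1.69, adjusted p = 0.000598 and 0.440 with an estimated correlation). None of its 6 tested members passed over all miRNAs and 4 passed adjusted over the list alone. miR-322* had a log2 difference of 2.50 (adjusted p = 0.0688) and miR-542-3p of 1.64 (adjusted p = 0.0930).

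The miR-200 family, which maintains the epithelial state by repressing Zeb1 and Zeb2, was at the floor in both sarcomatoid tumours and at widely different levels in the epithelioid ones. In SM 1, 1 of its 5 members was nonetheless detected, and in SM 2 0 were. The mean level of the family was -1.62 in EM 3, -4.35 in EM 2, -5.82 in EM 4 and -6.10 in EM 1, against a floor of -7.64. miR-200a and miR-200b were detected on all 4 EM arrays and on no SM array, which gave differences of at least 13.8-fold and 13.6-fold (adjusted p = 0.10 and 0.127). None of the 5 members passed over all miRNAs and 3 passed adjusted over the list alone. The set test gave an adjusted p of 0.0459 at a median log2 difference of -3.19 (-4.03 without EM 1), but 0.283 by fry and 0.770 with an estimated correlation. It ended at 0.149 without EM 2, 0.0624 without SM 1, 0.111 without SM 2 and 0.339 with the slide row as a block. RPMC was at the floor as well, and MTC had -1.37.

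The imprinted Dlk1-Dio3 cluster, a large group of miRNAs on chromosome 6, was lower as a set in SM (median log2 difference -1.43, adjusted p = 0.00106, but 0.336 by fry and 0.770 with an estimated correlation), although none of its 25 tested members passed. Beside miR-494, 1 of its 47 other miRNAs was detected on each SM array, against 21 in EM 1 and 24 in each of EM 2, EM 3 and EM 4. miR-300-3p and miR-341 were detected on all 4 EM arrays and on neither SM array, with differences of at least 8.03-fold and 3.30-fold (adjusted p = 0.155 and 0.204). With the slide row as a block the adjusted p of the set was 0.145. The miR-29 family, repressors of collagen genes, was lower as a set (median -1.44, adjusted p = 0.0103, and 0.440 with an estimated correlation). None of its 4 members passed over all miRNAs and all 4 passed adjusted over the list alone, with log2 differences of -1.85 for miR-29c and -1.47 for miR-29b. The miR-30 family was lower as a set (median -0.83, adjusted p = 0.00118, and 0.440 with an estimated correlation), with none of 10 members past the threshold over all miRNAs, 3 adjusted over the list alone, and values of -0.91 for miR-30c and -1.32 for miR-30c-2*.

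No other list passed camera in SM against EM. The adjusted p was 0.0878 for the let-7 family (let-7b 0.77, let-7d 0.52), 0.909 for the proliferation-linked miR-17-92 cluster and its paralogs (miR-19b -0.53, miR-93 0.40) and 0.893 for the p53-induced miR-34 family, of which 0 of 3 members passed (miR-34a -0.092, miR-34b 0.23, miR-34c 0.50). For the singles linked to TGF-beta, cancer and hypoxia it was 0.202. Among them miR-221 had a log2 difference of 1.24, the hypoxia miRNA miR-210 of -2.72, miR-21 of 0.44 (SE 0.24), miR-21* of 0.53 and miR-31 of 2.12 with an SE of 2.05, none of which passed. The reported regulators of iron genes had 0.622, with miR-152 the member past the threshold. The iron list's mean was -0.58, and that of the miR-17-92 list -0.018, although both set tests pointed upward. Apart from miR-152, no member of these lists passed adjusted over the list alone. Among the miRNAs next below the threshold were miR-326 (-1.48), miR-185 (-0.73) and miR-101a (-1.04).

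Markers of other cell types were compared to see what else the samples held. The striated muscle list averaged -1.20 in EM 4, -2.34 in SM 2 and -3.46 in EM 2, but -7.05 in EM 1 and -7.44 in SM 1, and the unscaled signal of miR-1 was 38169, 28234 and 7882 in the first 3 of these arrays and 21.4 in EM 1. As a list it did not pass (adjusted p = 0.893; miR-499 -0.84, miR-1* -0.46), nor did the leukocyte (0.622; miR-146a 0.73, miR-150 -0.45), neural (0.996; miR-212 0.98, miR-132 -0.997), squamous and gland epithelium (0.241; miR-205 -1.55, miR-96 at least 6.16-fold lower in SM), and liver, pancreas and gut lists (0.893; miR-192 -0.31, miR-194 -0.17). The smooth muscle and stroma miRNAs miR-143 (-1.06, SE 0.76) and miR-145 (-0.97, SE 0.75), the endothelial miR-126 (0.12) and the erythroid miR-144 (1.25) and miR-451 (0.88) did not pass, and these lists had too few members for a set test.

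**Figure D2:**
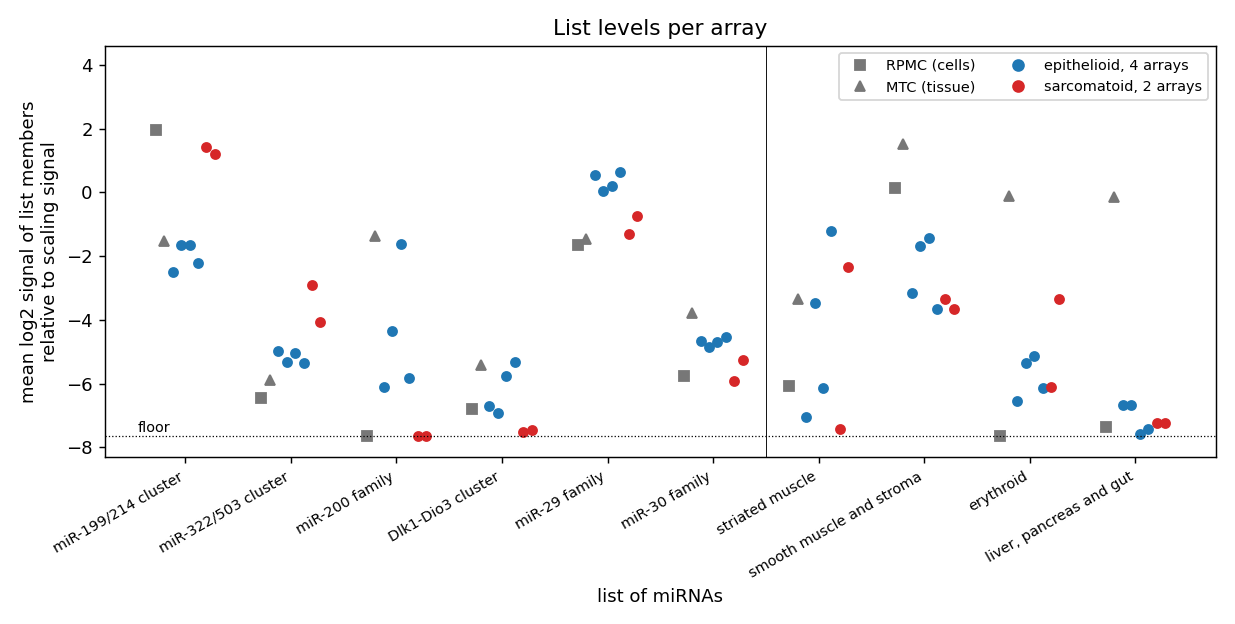
Each point is the mean log2 signal of a list's members on 1 array relative to the scaling signal, with lists described for tumour subtypes left of the vertical line and markers of other cell types right of it. RPMC and MTC lie far apart for the miR-200 family, the erythroid list and the liver, pancreas and gut list, and the striated muscle list spans -7.44 to -1.20 within the tumours.

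Tumours as a whole, taken as the mean of both subtypes, were compared with the non-neoplastic pair to find miRNAs that differ between mesothelioma and mesothelium. Members of the miR-322/miR-503 cluster were higher in the tumours, with miR-503 at 8.45-fold (-4.94 ± 0.72, SD, n = 4, in EM and -2.88 ± 0.0017, SD, n = 2, in SM against -6.99 ± 0.92, SD, n = 2), miR-322 at 5.66-fold and miR-542-3p at 4.99-fold. Neither miR-503, at the floor there, nor miR-542-3p was detected in RPMC, so the sizes of their 2 folds depend on signals below detection. miR-195 and miR-497, a related pair of cell cycle repressors, rose 4.87-fold and 4.26-fold, and miR-29b rose 2.82-fold. miR-145, the smooth muscle miRNA, was 24.8-fold lower, miR-196c 23.1-fold and miR-494 97.6-fold lower. Members of the miR-17-92 cluster fell too, among them miR-18a (7.06-fold), miR-17-5p (6.85-fold) and miR-92a (-2.27 in log2 units). MTC carried strong signals of liver and blood, with log2 values of 5.26 for the hepatocyte miRNA miR-122 and 1.13 for the erythroid miR-451, against -4.94 and -2.15 in the highest tumours.

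Of 241 tested miRNAs, 39 passed the limma test, 6 higher and 33 lower in the tumours, and 66 had an unadjusted p under 0.05. The median log2 difference of all tested miRNAs was -0.69, and relative to it miR-503 was 3.77 higher, miR-195 2.98 and miR-29b 2.19 higher, while miR-145 stood at -3.94 and miR-18a at -2.13. The lowest adjusted p was 0.0261, reached among others by miR-145 (SE 0.67), miR-196c (SE 0.83), miR-409-3p (-2.77) and miR-193* (-2.98), the last of which was at the floor on all 6 tumour arrays, so that its difference depends on the floor. Further falls were miR-333 (-3.84), miR-874 (-3.86), miR-365 (-2.88), miR-1* (-2.62) and let-7b* (-2.60). miR-494, of the Dlk1-Dio3 cluster, differed between its non-neoplastic arrays by more than the tumours did, at 6.64 in MTC and 1.11 in RPMC. Without RPMC and without MTC the differences were, in this order, -9.38 and -3.84 for miR-494, 2.43 and 3.73 for miR-503, 1.78 and 3.22 for miR-322, 1.40 and 3.24 for miR-542-3p, 1.67 and 2.90 for miR-195, -5.36 and -2.35 for miR-874, -2.92 and -4.77 for miR-333, -2.19 and -3.76 for miR-193* and -1.86 and -3.89 for miR-365. That of miR-196c was -3.93 without SM 1 and -5.14 without SM 2. At least as many alternatives ended the call as kept it for miR-874 (15 of 22), miR-333 (14 of 22), miR-494 (12 of 24) and miR-542-3p (11 of 23, with 1 more in which it turned). Of the 33 falls, 22 were in miRNAs with a geometric mean of the unscaled signal under 100. The other 11 falls had at least 100, as had 91 of all 241 tested miRNAs.

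The scaling signal of the tumours was 5.56-fold that of the non-neoplastic arrays, and the number of falls moved with the scaling. The split of higher to lower calls was 6 to 33 with the scaling used, 10 to 1 with the percentile over all miRNAs, 9 to 3 with quantile normalization, 7 to 1 with median scaling and 6 to 191 with normexp, and the authors' value table gave 2 to 0. With normexp the differences of miR-503 and miR-542-3p turned, to -0.48 and -0.67. The normexp setting added an offset of 50 to each spot. Against scaling signals of 597 in RPMC, 1008 in MTC and 3049 to 7122 in the tumours, that weighs more in the non-neoplastic arrays. Falls and turns under normexp can therefore not be told apart from an effect of the offset. No miRNA passed without EM 1 (62 at an unadjusted p under 0.05), EM 3 (60), SM 1 (54) or SM 2 (59) by limma, 15 passed without EM 4, 14 with EM 3 and EM 4 averaged, 72 without RPMC and 66 without MTC; with the slide row as a block there were 30, and each row held 1 non-neoplastic array, too few for a test within it.

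**Figure D3:**
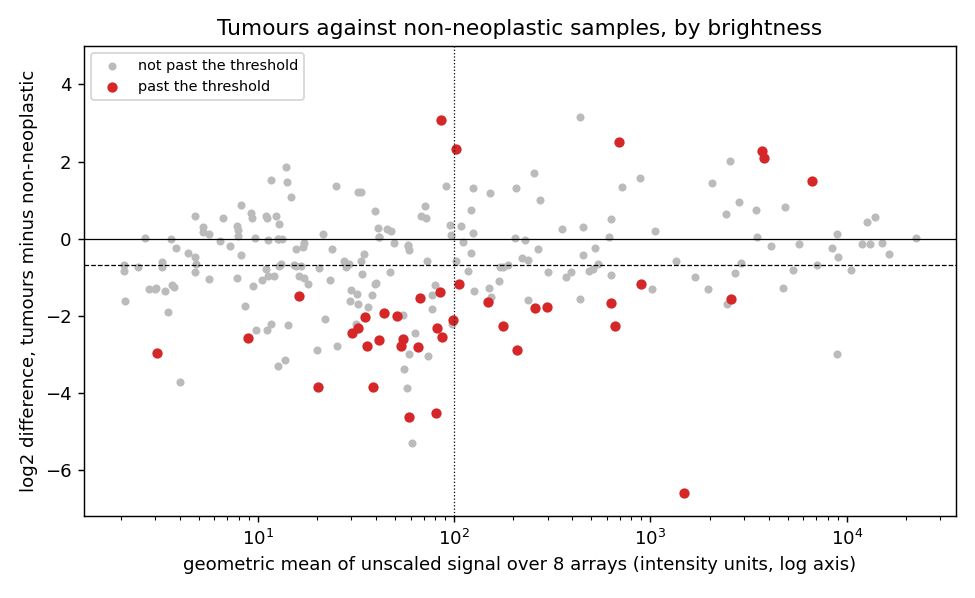
Each point is 1 of 241 tested miRNAs, with the geometric mean of its unscaled signal over the 8 arrays on a log axis and the log2 difference of tumours minus non-neoplastic samples on the vertical axis; the dashed line is the median of all tested miRNAs and the dotted line an unscaled signal of 100. Of the 33 miRNAs past the threshold below 0, 22 lie left of the dotted line and 11 right of it, where 91 of all 241 lie.

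Of the lists, 3 passed camera in this comparison and none with an estimated correlation. The miR-322/miR-503 cluster was higher (median 1.84, 2.53 relative to all tested miRNAs, but -0.81 with normexp, where the median of all was -1.68), with 3 of 6 members past the threshold over all miRNAs and 4 adjusted over the list alone (set test adjusted p = 3.78e-06, and 0.145 with an estimated correlation). The miR-29 family was higher (median 1.18, 1.87 relative to all), with 1 of 4 members over all miRNAs and 2 over the list alone (adjusted p = 0.00205, and 0.145 with an estimated correlation). For EM alone the miR-29 median was 1.90 (camera adjusted p = 0.000393, and 0.116 with an estimated correlation). For SM alone it was 0.47 (camera adjusted p = 0.0928), with 0 members past the threshold over the list alone. The miR-17-92 cluster and paralogs were lower (median -1.57, -0.88 relative to all), with 5 of 11 members over all miRNAs and 6 over the list alone (adjusted p = 0.00652, and 0.851 with an estimated correlation). Its median was -2.28 without RPMC, and without MTC -1.07 with an adjusted p of 0.173, where the miR-29 family had 0.118. The miR-199/miR-214 cluster did not pass (adjusted p = 0.836), and its members differed by -0.14 (SE 0.58) for miR-199a-3p, -0.25 (SE 0.88) for miR-199a-5p and -1.31 (SE 1.14) for miR-214. Neither did miR-21 (0.030, SE 0.39), miR-21* (0.093), miR-31 (-3.05, SE 1.96) and the miR-34 family (miR-34a 0.94, miR-34b 1.01, miR-34c 0.59; list adjusted p = 0.337). The difference of miR-31 was -0.83 without RPMC and -5.27 without MTC.

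For the remaining lists the adjusted p was 0.965 for the miR-200 family (miR-429 -1.63), 0.692 for the let-7 family, of which let-7b* fell, 0.692 for the Dlk1-Dio3 cluster, of which miR-409-3p and miR-494 fell, 0.812 for the miR-30 family (miR-30d -0.87), 0.584 for the regulators of iron genes (miR-320 -1.45) and 0.836 for the TGF-beta, cancer and hypoxia singles. Among markers of other cell types it was 0.584 for striated muscle, 0.368 for leukocytes (miR-342-3p -1.51), 0.584 for the neural list (miR-212 -2.46), 0.478 for liver, pancreas and gut (miR-192 -3.86) and 0.823 for squamous and gland epithelium (miR-182 -1.30). miR-182 lay above the floor in RPMC alone, so its difference was set by that array and the floor. Of the lists too small for a set test, the endothelial miR-126 (1.34) and the erythroid miR-144 (-2.09) did not pass, and of the smooth muscle pair 1 passed over all miRNAs and 2 adjusted over the list alone. The counts adjusted over the list alone were otherwise those over all miRNAs, at 1 for let-7, 2 for Dlk1-Dio3 and 1 (miR-1*) for striated muscle. The falls of let-7b* and miR-1* depend on the scaling, as given above. The median and the direction of the set test differed in sign for the miR-199/miR-214, miR-200, Dlk1-Dio3 and miR-30 lists and the TGF-beta singles, since camera sets a list's moderated statistics against those of the other miRNAs. By fry the neural list (adjusted p = 0.0414) and the iron list (0.0348) passed in addition, both downward. Since fry tests against 0, the median of all tested miRNAs, -0.69, weighs in these calls. Relative to that median the 2 lists had medians of -0.90 and -0.53, and camera called neither. Without RPMC and without MTC the differences were, in this order, -7.47 and -0.25 for miR-192 and -1.34 and -3.58 for miR-212.

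Epithelioid tumours alone were compared with the non-neoplastic pair. Members of the miR-29 family rose, with miR-29c 7.72-fold higher (1.07 ± 0.27, SD, n = 4, against -1.88 ± 1.37, SD, n = 2) and miR-29b 4.69-fold higher. miR-10b, of the Hox clusters, rose 4.94-fold, miR-195 4.69-fold and miR-497 4.23-fold. The largest falls past the threshold were those of miR-196c (24.0-fold lower), miR-145 (17.7-fold), miR-18a (7.89-fold), miR-365 (7.86-fold) and miR-193*, at the floor in all tumours (-2.98 in log2 units), and MTC held the liver and blood signals given above. In all, 30 of 241 miRNAs passed, 5 higher and 25 lower, with adjusted p from 0.0284 upward, 71 had an unadjusted p under 0.05, and the median of all tested miRNAs was -0.58. Further falls were miR-17-5p (-2.77), miR-409-3p (-2.53), miR-484 (-2.53), miR-93 (-2.47), miR-347 (-2.41), miR-1* (-2.39) and let-7b* (-2.39). Those of miR-1* and let-7b* depend on the scaling, as in the mean of tumours. miR-214 (-3.11, SE 1.19), miR-199a-3p (-1.70), miR-199a-5p (-1.86), miR-31 (-4.11), miR-21 (-0.19), miR-21* (-0.17), miR-34a (0.99), miR-34b (0.90) and miR-34c (0.34) did not pass. The split of 5 to 25 became 7 to 0 with the percentile over all miRNAs, 6 to 1 with quantile normalization, 6 to 0 with median scaling and 6 to 189 with normexp, and 3 to 0 in the authors' value table, with none of those 3 among the 30. With EM 3 and EM 4 averaged, as their source names share a number, 0 passed by limma (63 at an unadjusted p under 0.05). By limma none passed without EM 1 (68 at an unadjusted p under 0.05), EM 3 (55), SM 1 (65) or SM 2 (64), 12 without EM 4, 63 without RPMC, 72 without MTC and 15 with the slide row as a block. Without RPMC and without MTC the differences were, in this order, 1.98 and 3.92 for miR-29c, 1.61 and 2.84 for miR-195, -2.19 and -3.76 for miR-193*, -1.96 and -3.99 for miR-365, -1.93 and -3.14 for miR-484, -1.73 and -3.22 for miR-93 and -3.07 and -1.75 for miR-347. For those not past the threshold they were -0.74 and -5.47 for miR-214, -0.65 and -2.76 for miR-199a-3p, -0.049 and -3.67 for miR-199a-5p and -1.89 and -6.33 for miR-31. The call was lost in at least as many alternatives as kept it for let-7b* (16 of 23), miR-347 (14 of 23), miR-17-5p (12 of 22) and miR-1* (12 of 22).

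Sarcomatoid tumours alone differed from the non-neoplastic pair at no miRNA by limma, with 59 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0517, for 241 tested. The highest moderated statistics were headed by the miR-322/miR-503 cluster, with miR-503 at 17.2-fold (-2.88 ± 0.0017, SD, n = 2, against -6.99 ± 0.92, SD, n = 2), miR-322 at 10.3-fold, miR-542-3p at 8.83-fold and miR-322* at 5.49-fold, with miR-195 (2.34), miR-497 (2.10), miR-181a (1.55) and miR-181b (1.36). The lowest statistics belonged to miR-145 (-5.12), miR-193* (-2.98), miR-409-3p (-3.02), miR-92a (-2.42), miR-324-3p (-1.83), miR-664 (-2.06), miR-1* (-2.85) and miR-185 (-1.76). miR-193* was at the floor on both SM arrays, so the size of its fall depended on the floor. miR-214 had a difference of 0.49 (SE 1.38), miR-199a-3p of 1.42, miR-199a-5p of 1.37, miR-31 of -1.99, miR-21 of 0.25, miR-21* of 0.36, miR-34a of 0.89, miR-34b of 1.12 and miR-34c of 0.84. MTC held the liver and blood signals given above, and the median of all tested miRNAs was -0.75. The split of higher to lower calls was 8 to 0 with the percentile over all miRNAs, 7 to 0 with quantile normalization, 3 to 0 with median scaling, and 3 to 1 in the authors' value table, and with normexp 188 passed, 6 of them higher. The count was 74 without RPMC, 53 without MTC, 4 without EM 2, 8 without EM 4, 1 with EM 3 and EM 4 averaged and 0 with the slide row as a block (55 at an unadjusted p under 0.05 by limma). Without RPMC, where miR-503 and miR-542-3p were not detected, and without MTC the differences were, in this order, 3.46 and 4.76 for miR-503, 2.65 and 4.09 for miR-322, 2.23 and 4.06 for miR-542-3p, 1.73 and 2.96 for miR-195, 3.06 and 1.85 for miR-322*, -2.19 and -3.76 for miR-193* and 2.47 and 0.36 for miR-199a-3p.

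The 2 non-neoplastic samples differed in kind and had 1 array each, so their comparison has no replicate check. MTC held markers of liver, gut, blood and muscle that were not detected in RPMC. miR-122 was at least 3791-fold higher in MTC, miR-192 at least 149-fold, miR-215 at least 99.3-fold, miR-1 at least 84.7-fold, miR-327 at least 68.2-fold, miR-200c at least 67.1-fold and miR-194 at least 54.8-fold, all not detected in RPMC, where miR-451 was at the floor as well. RPMC had more of the mesenchymal miR-214 and of several other miRNAs, with miR-214 26.6-fold, miR-31 21.8-fold, miR-221 29.9-fold and miR-125b-5p 13.0-fold above MTC. miR-132, miR-207, miR-222 and miR-34c were not detected in MTC and at least 73.0-fold, 33.0-fold, 25.9-fold and 12.1-fold higher in RPMC. Of the miRNAs detected in either, 61 were at least 4-fold higher in MTC and 25 in RPMC, which became 34 and 40 with the percentile over all miRNAs, and 37 and 37 with quantile normalization.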

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

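Among the 4 EM arrays, 86 miRNAs and 2 measures per array were checked for 1 array far from the rest, and 3 miRNAs had a gap to the nearest array above 0.829 of the group's whole range. Chance alone exceeds that value in about 1 in 20 groups, a rate that the 3 of 86 miRNAs did not exceed. miR-181a, higher in SM, in EM 2 stood at -4.34, against -3.75 to -3.66 on the other EM arrays, a gap of 0.866 of the group's range. miR-92a, of the miR-17-92 cluster, in EM 1 stood at -1.90, against -2.79 to -2.66 on the other EM arrays, a gap of 0.854 of the group's range. miR-29c*, the passenger strand of miR-29c, in EM 4 stood at -3.92, against -4.84 to -4.70 on the other EM arrays, a gap of 0.844 of the group's range. The 3 miRNAs differed in 3 different arrays. No biological explanation was tested for them.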

How the results depend on the processing

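The slide row block and the filter at an unscaled geometric mean of 100 were the alternatives added after the data were examined, and slide and scan could not be used as blocks, since there was 1 of each. The median difference of the miR-199/miR-214 cluster in SM against EM was above 0 in each alternative run. It ranged from 3.03 to 3.44 over the arrays left out in turn, and its set test gave an adjusted p of 0.440 with an estimated correlation at the same median of 3.23. With that correlation 0 lists passed in SM against EM and 0 in tumours against non-neoplastic, and with fry 5 in the latter and 4 in the former, where the miR-200 family (0.283) and the Dlk1-Dio3 cluster (0.336) lost their call. Lists past the threshold lost their call in these cases. The miR-200 family had adjusted p of 0.194 with median scaling, 0.132 with normexp, 0.104 with a floor of 2 times its value and 0.0547 with all 8 samples. In the authors' value table the miR-29 and miR-30 families had 0.0891 and 0.0774 in SM against EM, and with normexp the miR-30 family had 0.0632. Against the non-neoplastic pair the tumours' miR-17-92 list had 0.245 with normexp, 0.111 in the authors' table, 0.142 with no filter, 0.0661 with detection on all arrays and 0.173 without MTC. The miR-322/miR-503 list had 0.245 with normexp and the miR-29 family 0.118 without MTC. Lists and miRNAs with no member left under a stricter filter gave no value. Dim miRNAs are limited by their signal over background: of the 33 falls in tumours, 22 had an unscaled geometric mean under 100. The other 11 had at least 100, as had 91 of all 241 tested miRNAs.

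The median of all tested miRNAs in SM against EM, -0.25 as reported, was -0.099 with the percentile over all miRNAs, -0.11 with quantile normalization, -0.45 with median scaling and -0.13 with normexp. In tumours against non-neoplastic it was 0.24 with the percentile over all miRNAs, -0.050 with quantile normalization, 0.041 with median scaling and -1.68 with normexp, in EM against non-neoplastic 0.25 with the percentile over all miRNAs, 0.073 with quantile normalization, 0.21 with median scaling and -1.61 with normexp, and in SM against non-neoplastic 0 with the percentile over all miRNAs, -0.14 with quantile normalization, -0.20 with median scaling and -1.77 with normexp. With the percentile over all miRNAs, the count was 5 in SM against EM, 7 in EM against non-neoplastic, 8 in SM against non-neoplastic and 11 in tumours against non-neoplastic. With quantile normalization, the count was 15 in SM against EM, 7 in EM against non-neoplastic, 7 in SM against non-neoplastic and 12 in tumours against non-neoplastic. With median scaling, the count was 20 in SM against EM, 6 in EM against non-neoplastic, 3 in SM against non-neoplastic and 8 in tumours against non-neoplastic. With normexp, the count was 195 in EM against non-neoplastic, 188 in SM against non-neoplastic and 197 in tumours against non-neoplastic. With a floor of 0.5 times its value, the count was 5 in SM against EM. With a floor of 2 times its value, the count was 26 in SM against non-neoplastic. In the authors' value table, the count was 30 in SM against EM, 3 in EM against non-neoplastic, 4 in SM against non-neoplastic and 2 in tumours against non-neoplastic. With no filter, the count was 17 in SM against non-neoplastic. With detection on all arrays, the count was 50 in EM against non-neoplastic and 28 in SM against non-neoplastic. With EM 3 and EM 4 averaged, the count was 0 in EM against non-neoplastic, 1 in SM against non-neoplastic and 14 in tumours against non-neoplastic. With all 8 samples in the fit, the count was 2 in SM against EM. With the slide row as a block, the count was 1 in SM against EM and 15 in EM against non-neoplastic. With unscaled geometric means of at least 100, the count was 15 in SM against EM, 17 in EM against non-neoplastic, 11 in SM against non-neoplastic and 20 in tumours against non-neoplastic. With a mean-variance trend, the count was 18 in EM against non-neoplastic and 5 in SM against non-neoplastic. With RPMC and MTC as separate groups, the count was 87 in EM against non-neoplastic, 73 in SM against non-neoplastic and 81 in tumours against non-neoplastic. With the deposited total signal per miRNA, the count was 9 in SM against non-neoplastic. With the mean of log2 probe signals, the count was 14 in SM against non-neoplastic. Of the miRNAs past the threshold in the authors' table, 0 were among the 30 of EM against non-neoplastic and 0 among the 39 of tumours against non-neoplastic. The count of 0 with EM 3 and EM 4 averaged is by limma, with 63 at an unadjusted p under 0.05. Counts given neither here nor in the report stayed within 1.5 times the reported one. In MTC against RPMC, 34 miRNAs were at least 4-fold higher in MTC and 40 in RPMC with the percentile over all miRNAs, and 37 in MTC with quantile normalization. The cause of these changes was not tested here.

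The replicate numbers of EM and SM were shared by 2 pairs, whose deviations from the group means correlated at r = 0.400 and 0.167, and nothing in the labels says what a number marks, so the numbers were not taken as pairs. With the replicate block 0 miRNAs passed limma's test in SM against EM (20 at an unadjusted p under 0.05). Under the block, turned results in SM against EM were miR-1* (0.0014), and the lists miR-17-92 (-0.15), striated muscle (0.25) and neural (0.0026). No paired analysis was possible because RPMC and MTC were numbered in accession order, for the comparisons against the non-neoplastic pair.

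Of the results on named miRNAs under the alternatives, 2379 kept direction and side of the threshold, 420 lost the call and 97 turned, of which 9 passed before or after. For lists, 596 were the same and 67 turned by the direction of the set test, of which 0 had passed. The value given for a list is its median, which can keep its sign when the set test turns. With the percentile over all miRNAs, the turned result in SM against EM was miR-34a (0.10). EM against non-neoplastic had miR-21 (0.90) and miR-21* (0.79). For tumours against non-neoplastic they were miR-199a-3p (1.04), miR-199a-5p (0.94) and miR-30d (0.31), and the lists miR-200 family (-0.90), let-7 family (0.38), Dlk1-Dio3 cluster (0.26) and striated muscle (1.22). With quantile normalization, turned results in SM against EM were miR-145 (0.10), miR-1* (0.70), miR-150 (0.37) and miR-192 (0.69), and the lists striated muscle (-0.13), liver (0.64) and neural (-0.22). As to EM against non-neoplastic, they were miR-21 (0.22) and miR-21* (0.64). In tumours against non-neoplastic they were miR-199a-3p (0.57), miR-199a-5p (0.53) and miR-30d (0.41), and the lists miR-200 family (-0.97) and Dlk1-Dio3 cluster (0.049). With median scaling, turned results in SM against EM were miR-34b (-0.11) and miR-126 (-0.22), and the lists miR-17-92 (-0.27), leukocyte (-0.23) and neural (-0.61). The turned ones in EM against non-neoplastic were miR-21 (0.86) and miR-21* (0.87). Among results of tumours against non-neoplastic, those turned were miR-199a-3p (0.73), miR-199a-5p (0.63) and miR-30d (0.00092), and the lists miR-200 family (-1.15), let-7 family (0.073) and Dlk1-Dio3 cluster (0.21). With normexp, turned results in SM against EM were miR-181a* (-0.014) and miR-34c (-0.067), and the lists miR-17-92 (-0.075) and striated muscle (-0.096). Turned in EM against non-neoplastic were miR-34b (-0.42) and miR-34c (-1.33). Also turned in SM against non-neoplastic were miR-542-3p (-0.12), miR-322* (-0.79), miR-181b (-0.66), miR-21* (-1.69), miR-34b (-0.40) and miR-34c (-1.39). The turned ones in tumours against non-neoplastic were miR-503 (-0.48), miR-542-3p (-0.67), miR-21* (-1.74), miR-34b (-0.41), miR-34c (-1.36) and miR-126 (-0.12), and the lists let-7 family (-0.67), Dlk1-Dio3 cluster (-1.65), miR-30 family (-1.52) and iron (-1.48). With a floor of 2 times its value, the turned result in SM against EM was the list miR-17-92 (0). In the authors' value table, turned results in SM against EM were miR-145 (0.41), and the list liver (-0.44). Among results of EM against non-neoplastic, those turned were miR-21 (0.28) and miR-21* (2.77). As to tumours against non-neoplastic, they were miR-199a-3p (0.31) and miR-199a-5p (0.22), and the lists miR-200 family (-2.46) and Dlk1-Dio3 cluster (-0.99). With no filter, the turned result in SM against EM was the list neural (0). Also turned in tumours against non-neoplastic was the list miR-200 family (-1.63). With detection on all arrays, turned results in SM against EM were the lists miR-17-92 (0.075) and miR-34 family (0.23). With EM 3 and EM 4 averaged, the turned result in SM against EM was the list miR-17-92 (-0.034). EM against non-neoplastic had miR-34c (-0.0088). For tumours against non-neoplastic it was the list miR-200 family (-1.76). With all 8 samples in the fit, turned results in SM against EM were the lists liver (-0.17) and neural (-0.27). With the slide row as a block, turned results in SM against EM were miR-34a (0.28) and miR-126 (-0.23), and the lists miR-17-92 (-0.51), striated muscle (2.27), leukocyte (-0.35) and neural (0.17). Turned in EM against non-neoplastic was miR-21* (0.28). Also turned in SM against non-neoplastic were miR-214 (-0.21), miR-21 (-0.092) and miR-21* (-0.55). The turned ones in tumours against non-neoplastic were miR-21 (-0.055) and miR-21* (-0.13), and the list cancer and hypoxia singles (-1.17). With unscaled geometric means of at least 100, the turned result in SM against EM was the list miR-17-92 (0.020). With RPMC and MTC as separate groups, the turned result in tumours against non-neoplastic was the list miR-199/miR-214 cluster (-0.25). With the mean of log2 probe signals, the turned result in SM against non-neoplastic was miR-21* (-0.0030). Tumours against non-neoplastic had miR-21 (-0.18) and miR-21* (-0.17).

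Each array was also left out in turn, and the ranges of the counts and of the results that turned in at least 1 case follow. The count in SM against EM ranged from 0 to 8. The miRNA differences in SM against EM ranged from -1.37 to 5.60 for miR-31, from -0.55 to 0.37 for miR-34a, from -0.55 to 0.93 for miR-34b, from -0.23 to 1.20 for miR-34c, from -0.069 to 0.87 for miR-93, from -0.13 to 0.36 for miR-126 and from -0.17 to 2.67 for miR-144. Other miRNA differences there ranged from -0.48 to 2.24 for miR-451. The list medians in SM against EM ranged from -0.18 to 0.20 for miR-17-92, from -0.23 to 0.93 for miR-34 family, from -2.36 to 2.17 for striated muscle, from -0.46 to -0.085 for liver and from -0.55 to -0.046 for neural. The count in EM against non-neoplastic ranged from 0 to 72. The miRNA differences in EM against non-neoplastic ranged from -0.68 to 0.30 for miR-21, from -1.93 to 1.59 for miR-21*, from -0.84 to 2.81 for miR-34a, from -0.73 to 2.52 for miR-34b and from -1.66 to 2.34 for miR-34c. The count in SM against non-neoplastic ranged from 0 to 74. The miRNA differences in SM against non-neoplastic ranged from -0.44 to 3.18 for miR-199a-5p, from -1.88 to 2.86 for miR-214, from -5.48 to 1.49 for miR-31, from -0.24 to 0.74 for miR-21, from -1.40 to 2.12 for miR-21*, from -0.93 to 2.72 for miR-34a and from -0.50 to 2.75 for miR-34b. Other miRNA differences there ranged from -1.16 to 2.84 for miR-34c. The count in tumours against non-neoplastic ranged from 0 to 72. The miRNA differences in tumours against non-neoplastic ranged from -1.20 to 0.91 for miR-199a-3p, from -2.06 to 1.57 for miR-199a-5p, from -3.67 to 1.06 for miR-214, from -0.46 to 0.52 for miR-21, from -1.67 to 1.85 for miR-21*, from -0.89 to 2.77 for miR-34a and from -0.61 to 2.63 for miR-34b. Other miRNA differences there ranged from -1.41 to 2.59 for miR-34c, from -4.85 to 1.60 for miR-429, from -1.16 to 3.83 for miR-126 and from -5.25 to 1.06 for miR-144. The list medians in tumours against non-neoplastic ranged from -2.06 to 1.06 for miR-199/miR-214 cluster, from -4.82 to 1.60 for miR-200 family, from -1.04 to -0.22 for let-7 family, from -0.89 to 2.63 for miR-34 family, from -1.13 to 0.69 for miR-30 family, from -1.09 to 1.79 for leukocyte and from -7.47 to 0.087 for liver. Other list medians there ranged from -2.43 to -1.34 for neural, from -2.54 to 0.94 for cancer and hypoxia singles and from -1.39 to -0.41 for iron. Among miRNAs of SM against EM that were not called and did not turn, those moved by over 1.5-fold ranged from -4.16 to -3.11 for miR-200a, from -4.11 to -2.95 for miR-200b, from 1.04 to 2.25 for miR-542-3p, from -3.31 to -1.92 for miR-96, from 0.63 to 1.85 for miR-221 and from -3.58 to -1.86 for miR-210. Among miRNAs of tumours against non-neoplastic that were not called and did not turn, those moved by over 1.5-fold ranged from -5.27 to -0.83 for miR-31, from -7.47 to -0.25 for miR-192, from -3.58 to -1.34 for miR-212 and from -2.60 to -1.30 for miR-182. Medians of lists whose set test kept its direction there ranged from -0.78 to 0.51 for Dlk1-Dio3 cluster and from -1.56 to 1.39 for striated muscle.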

Other observations

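The tests in this part were chosen after the results they bear on had been seen, except that the alternative scalings they use were planned before. Single arrays of a subtype differed in miRNAs tied to invasion, hypoxia and other tissues. miR-31 stood at -0.67 in SM 1 and at the floor in SM 2, at -6.60, -5.96, -4.89 and -7.64 in EM 1 to EM 4, and at 0.060 in RPMC. The hypoxia miRNA miR-210 was at -1.25, -3.80, -1.99 and -1.47 in EM 1 to EM 4 and at -5.71 and -3.98 in SM 1 and SM 2. The erythroid pair miR-144 and miR-451 averaged -3.34 in SM 2, -6.12 in SM 1 and between -6.54 and -5.14 in EM. The endothelial miR-126 lay between -1.96 and -1.31 in all 6 tumours, at -0.45 in MTC and at -5.45 in RPMC.

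The 33 falls in tumours against the non-neoplastic pair had a median log2 difference of -2.32 (median SE 0.50) with the scaling used and of -1.28 (median SE 0.52) after quantile normalization, where all 33 stayed below 0 and 3 passed. With the percentile over all miRNAs 31 stayed below 0 (median -1.14) and 1 passed, and with median scaling all 33 (median -1.42) and 1 passed. The calls ended because the differences shrank at a similar SE, and how much of the falls the scaling makes cannot be told apart from a true difference. Arrays with a larger scaling signal could push down miRNAs whose unscaled signal stays near-constant, giving a low slope of log2 unscaled on log2 scaling signal. Over the 6 tumours the median slope was 0.845 for the 11 bright falls (quartiles 0.698 and 0.961), against 0.769 in bright miRNAs that did not pass. Within the tumours the signal of most bright falls was therefore not near-constant. The slopes leave out RPMC and MTC, so they cannot decide this between tumours and non-neoplastic samples. There the bright falls had a median unscaled signal 0.71 higher in the tumours in log2 units, while the scaling signal was 2.47 higher. For the 22 dim falls the median slope was 0.841 (quartiles 0.354 and 1.65), against 0.852 in dim miRNAs that did not pass. With values so close to background, near-constant signal cannot be told apart from a true fall in them. A smaller amount of miRNA in the non-neoplastic samples and a biological difference stay open, untested.

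The 8 rises in SM against EM were set against the slide row and the amount of stroma. With the slide row as a block their median log2 difference was 2.61 (median SE 0.37), against 2.83 (median SE 0.26) without it, and 1 of the 8 passed at the wider SE. EM 1 was the single EM array in the row of both SM arrays, so the blocked difference is that of SM minus EM 1 alone. The test that called the 8 also favours EM arrays that agree. An effect of the row can therefore not be told apart from one of the subtype. The smooth muscle and stroma miRNAs miR-143 and miR-145 differed by a mean of -1.01 in log2 units, below 0 while the median rise was 2.83. The mesothelial cell culture RPMC had the pair at 0.13, above every tumour (-3.66 to -1.42), so it does not mark stroma alone here. The amount of stroma in SM can therefore not be judged from the pair. Of the 15 splits of the 6 tumours into 4 and 2, 1, the real one, gave 9 miRNAs, the highest other being 8 with EM 3 and EM 4 apart, whose source names share a number, and the splits are too few for a share under 0.05; a difference of the subtypes themselves stays open.

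miR-494 took 37.2% of the signal of MTC, at 6.64 against 0.063 in the highest tumour. Each of its 2 probes was raised, the lesser by 550-fold over the median of the other 7 arrays, which argues against 1 aberrant probe. The other members of the Dlk1-Dio3 cluster (n = 28) averaged -5.84 in MTC. This was -0.42 (SE 0.38) relative to EM 4, 0.0016 to EM 3, 1.01 to EM 1 and 1.33 to EM 2. It was 1.25 relative to RPMC and up to 1.80 (SE 0.26) to the SM arrays. Of the 47 others on the array, RPMC had 3 detected and each SM array 1, so the floor limits these differences. The SE is over members, which are not independent replicates. For miR-494 the same differences were 5.54 to 10.60, and 6.58 to 9.79 relative to the EM arrays. The values relative to EM argue against a rise of the whole cluster as large as that of miR-494. A lesser rise of the cluster, binding of other RNA of the tissue to these probes and a release of miR-494 alone stay open, and no biological explanation was tested.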
